A study of Mus musculus with 12 samples.

How the data were processed

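Total RNA was measured by RNA sequencing in primary cultures of mouse dorsal root ganglion (DRG), the ganglion that holds the cell bodies of sensory neurons together with glia, fibroblasts and vascular cells. Per the labels' protocols, RNA was purified with the RNeasy Mini kit, libraries were made with a TruSeq Stranded RNA kit, and they were sequenced as paired 150-base reads on a NovaSeq S4 flow cell. Antisense oligonucleotides (ASOs) are short synthetic strands that pair with a chosen RNA. The ASO mix was directed at GI-SINE RNAs, transcripts of B2 repeats (short interspersed elements transcribed by RNA polymerase III) that the study's title calls growth inducing. The 12 libraries form 3 groups of 4: cultures given the GI-SINE ASO mix at 50 nM, cultures given a control ASO at 50 nM, and untransfected cultures. Per the series design, each replicate number is a separate culture prepared from 1 mouse and divided among the 3 conditions.

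The deposited table holds raw counts of reads per gene, made by the authors. The submitters' processing notes name bcl2fastq 2.17, STAR and HTSeq, the last 2 without versions, and the builds GRCm38 and mm10. The annotation release and the strand setting of the counting are not given in the sources used here, so counts of genes that overlap another gene are uncertain, as are those of paralogs and pseudogenes. The table has 48795 gene IDs. Of these, 48349 were matched to a symbol in GENCODE release 21 of mouse (build GRCm38), which also gave the coordinates. The 446 other IDs held at most 0.0458% of the counts of any library and stayed in the tests. The level of GI-SINE RNA itself was not analysed here, so whether the ASO mix lowered its target was not measured.

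Total counts ranged from 14864622 to 22704267 per library. Between 15.7% and 19.5% of each library's counts fell in Gm23935, Gm42418 and Gm26917, loci that collect ribosomal RNA reads. Every pair of libraries within a group differed by more than counting noise, so no library was treated as a copy of another.

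Genes were tested with edgeR 4.0.16 under R 4.3.3. Low counts were filtered by group with edgeR's default rule, which left 16831 genes, and libraries were scaled by the trimmed mean of M values. A robust quasi-likelihood model with group and mouse as terms was fitted to all 12 libraries, and adjusted p values are Benjamini-Hochberg values of its two-sided test over all tested genes. A gene was called changed at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) from that fit, and CPM (counts scaled to library size) is given as mean ± SD over 4 libraries. Mouse was a block in the main model because the series design states that the conditions of 1 number share a mouse. As a check, deviations from group means of libraries with the same number correlated at 0.138 to 0.557, and in 24 of 24 cases a library correlated best with its own number.

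Before the data were examined, 30 gene lists were fixed, covering cell types of the ganglion, regeneration, translation, stress and the RNA polymerase III machinery. The 29 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on voom log2 CPM values at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The list of other leukocyte markers had too few tested genes. Counts of list members "adjusted over the list alone" used only the genes of that list. Genes named in the text followed a rule also fixed beforehand. Among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and the same direction in all 4 mice, leaving out symbols that are only clone or predicted-gene numbers, it took the 8 largest rises, the 8 largest falls and the 4 smallest p values in each direction. Up to 4 members with the smallest p of each list described were added. Some genes that this rule names are not reported here.

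Alternatives fixed before the data were examined were a fit without the mouse, DESeq2 1.42.0 size factors in edgeR, DESeq2's Wald test, limma-voom, no filter and a stricter filter (at least 10 counts in 4 libraries and a mean log2 CPM of at least 1), a fit of only the compared groups, each mouse left out in turn, and a fold change of at least 1.5. For lists they were camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction. Scaling by library size only, removal of each library's trend in transcript length and GC content, and leaving out the 3 most abundant loci were added after seeing the data. On counts simulated for the comparison of the ASO mix with the control ASO (16469 genes), edgeR recovered 66% of genes changed 1.5-fold and 90% of genes changed 2-fold, and called 13 unchanged genes. Camera called 5 of 5 shifted lists and 1 of 21 lists without a shifted gene, and with an estimated correlation 5 and 0, as did fry. The gene simulation changed 200 genes, so it does not test scaling where most genes move. Genes were drawn independently, so it cannot judge the choice of correlation. For the closing section, 3' UTRs were searched with blastn for a 175-base B2 consensus sequence written from general knowledge, at a minimum match of 100 bases and 75% identity.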

Results

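The data are gene counts from 12 libraries of primary mouse DRG cultures of the C57/Bl6 wild type. Each of 4 mice gave 1 culture, which was divided among the GI-SINE ASO mix, the control ASO and no transfection. Total counts were 16416459 to 21250125 in the mix group, 14864622 to 22704267 in the control ASO group and 16971091 to 22668448 in the untransfected group, and 16831 genes were tested. On the first principal component of log2 CPM (57.3% of the variance), the mix libraries of mice 1 to 3 lay at 64.4 to 72.3 and that of mouse 4 at 25.9. The control ASO libraries lay between -15.3 and 0.30 and the untransfected libraries between -58.2 and -44.7. The third component (9.87%) set the 3 libraries of mouse 4 apart from the other 9.

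**Figure D1:**
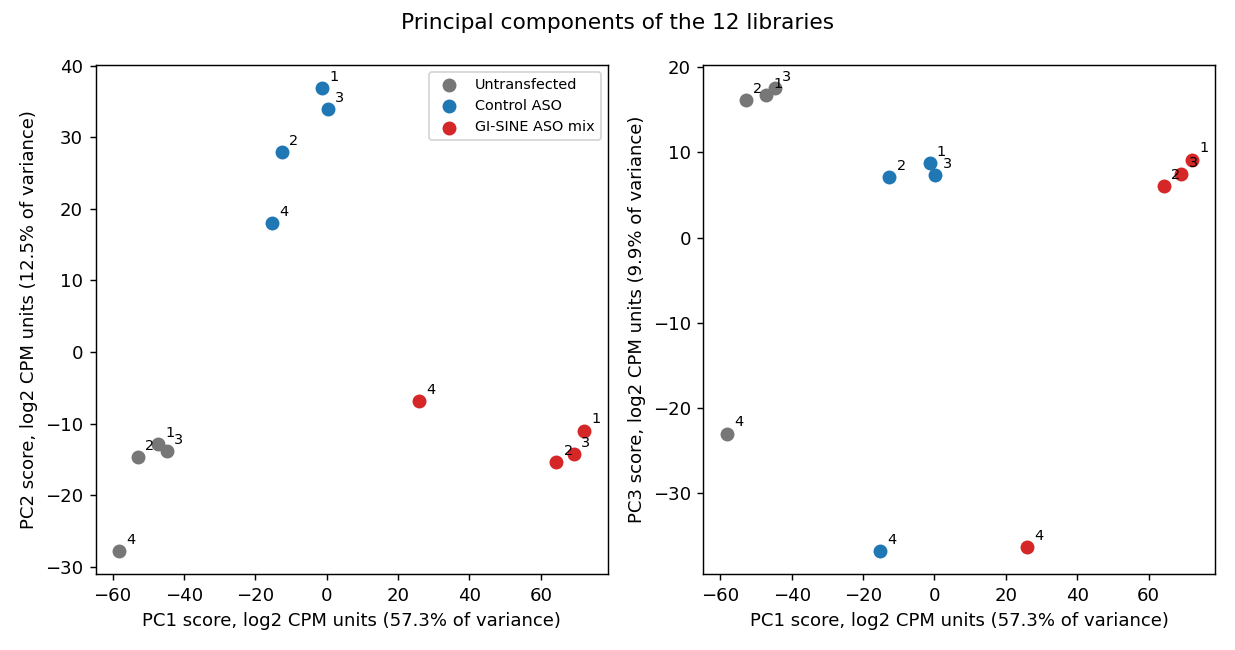
Scores of the 12 libraries on the first 3 principal components of log2 CPM, with each point labelled by mouse and coloured by group. Mix libraries lie to the right on the first component, with mouse 4 at 25.9, and the libraries of mouse 4 lie at -23.0 or lower on the third.

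The comparison of the GI-SINE ASO mix with the control ASO asks what changed when the ASOs were directed at GI-SINE RNA, beyond transfection with an ASO. With the mix, 12 of 17 nociceptor genes and 67 of 74 cytosolic ribosomal protein genes were higher and none lower, and 7 of 16 Schwann cell genes were lower and 4 higher. The first 2 lists were called by camera at a preset correlation but not with an estimated one (adjusted p = 0.445 for each), and the Schwann cell list was not called. Calca, the gene of the nociceptor peptide CGRP, rose by 1.03 ± 0.11 on the log2 scale (SE, 4 mice; 651 ± 178 against 312 ± 38.6 CPM, adjusted p = 3.67e-05). Erbb3, the neuregulin receptor of Schwann cells, fell by 3.59 ± 0.19 (1.79 ± 0.88 against 21.6 ± 9.25 CPM, adjusted p = 3.86e-08). Of the 16831 genes, 9454 changed, 4600 higher and 4854 lower, and the change was at least 2-fold in 836 higher and 552 lower genes.

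The smallest p values among higher genes belonged to Pcdh17, Fndc9, Gch1 and Fzd5. Pcdh17, a protocadherin gene (ENSMUSG00000035566, GRCm38 chromosome 14, 84443563 to 84539002), rose by 1.87 ± 0.08 on the log2 scale, from 51.4 ± 4.98 to 188 ± 26.5 CPM (adjusted p = 2.32e-10). Fndc9 rose by 3.29 ± 0.15, Gch1, the first enzyme of tetrahydrobiopterin synthesis, by 1.83 ± 0.09 and the Wnt receptor gene Fzd5 by 1.74 ± 0.09. The largest rises were in genes near the floor of detection in control cultures: Rnf225 (5.12 ± 0.48), Rpl3l (4.83 ± 0.34), Ccdc24 (4.40 ± 0.52), Nhlh1 (4.39 ± 0.32), Ptprv (4.17 ± 0.38), Bcl6b (3.88 ± 0.80), Slc25a2 (3.79 ± 0.33) and AA474408 (3.72 ± 0.40). Their mean in the control ASO group was 0.207 to 0.823 CPM. Slc25a2 starts 1746 bases after the end of Taf7 on the same strand and Rpl3l 5891 bases after Rps2, while Ccdc24 overlaps B4galt2 and Slc6a9 and AA474408 overlaps Zfp143.

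The largest falls were in Heyl (-3.80 ± 0.64), a Notch target, Erbb3, P2rx7 (-3.58 ± 0.18), Rab7b (-3.40 ± 0.35), Layn (-3.39 ± 0.30), Pdlim4 (-3.23 ± 0.26), Olfml2a (-3.11 ± 0.51) and Plin3 (-3.06 ± 0.26). Some of these were scarce with the control ASO: Heyl lay at -0.38 to 1.53 log2 CPM and Rab7b at 0.38 to 1.36. Heyl then lay at -3.31 in the mix libraries of mice 1 and 2. Erbb3 and P2rx7 were less scarce there, at 3.73 to 4.90 and 2.97 to 4.45 log2 CPM. Heyl, Erbb3, P2rx7, Rab7b, Layn, Pdlim4 and Olfml2a were already lower with the control ASO than in the untransfected culture of each mouse. Plin3 was lower in that step in mice 1 and 3 but not in mice 2 and 4. P2rx7, an ATP-gated channel (ENSMUSG00000029468, chromosome 5, 122643911 to 122691432), went from 12.9 ± 6.33 to 1.07 ± 0.608 CPM (adjusted p = 4.59e-10). Shroom2 (-2.21 ± 0.14), Nde1 (-1.74 ± 0.12) and Rnf213 (-0.84 ± 0.06) had the next smallest p values among lower genes. Each gene named in this comparison moved in its direction in all 4 mice.

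The nociceptor list had a median log2 fold change of 0.73 (camera adjusted p = 0.000411, and adjusted p = 0.445 with an estimated correlation), with 12 members higher, among them Calca and the heat-gated channel Trpv1 (0.81 ± 0.10). Of 15 mechanoreceptor and proprioceptor genes, 9 were higher and 2 lower (adjusted p = 0.0294, and adjusted p = 0.445 with an estimated correlation), with Kcns1 at 1.29 ± 0.13 and the touch channel Piezo2 at 0.51 ± 0.05. Of 18 pan-neuronal markers, 9 were higher and 1 lower (median 0.16, adjusted p = 0.0431, and adjusted p = 0.445 with an estimated correlation), with Uchl1 at 0.44 ± 0.04 and Prph at 0.42 ± 0.05. The pan-neuronal call was lost without mouse 4 (adjusted p = 0.135) and the mechanoreceptor call without mouse 3 (adjusted p = 0.0732). Axon growth genes had 14 higher and 4 lower of 24 (adjusted p = 0.0220, and adjusted p = 0.445 with an estimated correlation) and regeneration-associated genes 15 higher and 5 lower of 30 (adjusted p = 0.0294, and adjusted p = 0.467 with an estimated correlation). For the mix against untransfected cultures camera called neither of these lists (adjusted p = 0.297 and 0.637). Stmn2 (0.40 ± 0.05), Stmn4 (0.52 ± 0.05) and the neuropeptide gene Gal (0.66 ± 0.08) were higher, and Dync1h1 (-0.52 ± 0.06) and Sema6a (-0.51 ± 0.06) were lower.

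Of 74 cytosolic ribosomal protein genes, 67 were higher and none lower (median 0.47, adjusted p = 1.95e-15, and adjusted p = 0.445 with an estimated correlation), and 71 were higher when adjusted over the list alone. Rplp0 rose by 0.64 ± 0.05. Of 29 nuclear genes of oxidative phosphorylation, 21 were higher and none lower (adjusted p = 1.17e-05, and adjusted p = 0.445 with an estimated correlation), with Ndufa4 at 0.69 ± 0.06 and Cox4i1 at 0.55 ± 0.06. Mitochondrially encoded genes were higher in 5 of 14 (adjusted p = 0.0294, and adjusted p = 0.547 with an estimated correlation), with mt-Co1 at 0.40 ± 0.08 and mt-Rnr2 at 0.54 ± 0.13. For the mix against untransfected cultures 1 of these genes was higher and the median of the list was -0.03. The p53 target list had 10 higher and 3 lower of 18 (adjusted p = 0.00440, and adjusted p = 0.445 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 0.68 ± 0.05, Aen at 1.06 ± 0.09 and the apoptosis gene Bax at 1.28 ± 0.12. Immediate early genes had 14 higher and 2 lower of 20 (adjusted p = 0.00411, and adjusted p = 0.445 with an estimated correlation), with Npas4 at 3.14 ± 0.38, Jun at 0.46 ± 0.06 and Nr4a1 at -0.84 ± 0.10. Npas4 was scarce, at -2.14 to -1.52 log2 CPM with the control ASO and 0.40 to 1.26 with the mix. Heat shock genes had 9 higher and 1 lower of 14 (adjusted p = 0.00459, and adjusted p = 0.445 with an estimated correlation), with Dnajb1 at 0.65 ± 0.06 and Hspb1 at 0.61 ± 0.06. Cholesterol genes had 13 higher and 1 lower of 21 (adjusted p = 0.00440, and adjusted p = 0.467 with an estimated correlation), with Sqle at 0.47 ± 0.06 and Hsd17b7 at -0.73 ± 0.09. The RNA polymerase III machinery was the only list called lower, with 1 higher and 13 lower of 23 (median -0.21, adjusted p = 0.0431, and adjusted p = 0.467 with an estimated correlation). In it Gtf3a was at -0.55 ± 0.09, Snapc3 at -0.61 ± 0.11 and Gtf3c4 at 0.70 ± 0.07. It lost its call without mouse 1 or mouse 3 (adjusted p = 0.0633 and 0.0776) and with the length and GC trend removed (adjusted p = 0.129), and the mitochondrial list without mouse 3 (adjusted p = 0.0870), with the trend removed (adjusted p = 0.278) and with fry (adjusted p = 0.0801). Removing the trend left the ribosomal and oxidative phosphorylation lists called but lowered their medians, from 0.47 to 0.29 and from 0.29 to 0.14.

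Camera at the preset correlation, with the scaling used throughout and all 4 mice, called none of the lists of other cell types. Fry called the fibroblast, mural cell and satellite glia lists lower (adjusted p = 0.00815, 0.00474 and 0.0221). Schwann cell genes had 4 higher and 7 lower of 16 (median -0.63, adjusted p = 0.193), with Ngfr, which sensory neurons also express, at 1.01 ± 0.07. Satellite glia markers had 3 higher and 5 lower of 12 (median 0.21, mean -0.49, tested direction down, adjusted p = 0.839), with Kcnj10 at -2.78 ± 0.20 and Fabp7 at -2.51 ± 0.22. Fibroblast genes had none higher and 6 lower of 15 (median -0.50, adjusted p = 0.0538), with Col1a2 at -2.08 ± 0.28 and Postn at -2.01 ± 0.35. This list was called lower without each mouse in turn (adjusted p = 0.0323, 0.0333, 0.0381 and 0.0415) and with DESeq2 size factors (adjusted p = 0.0481), but not without mouse as a block, with an estimated correlation (adjusted p = 0.445) or with the length and GC trend removed (adjusted p = 0.129). On voom values its median of -0.49 became -0.32 without mouse 1, -0.86 without mouse 3 and -0.31 with the trend removed. Mural cell markers had 1 higher and 5 lower of 9, and endothelial markers none higher and 3 lower of 10. Macrophage markers had 3 higher and none lower of 12 (median -0.19), with Cd68 at 1.10 ± 0.09. Interferon-stimulated genes had 3 higher and 10 lower of 27 (adjusted p = 0.0672), with Parp14 at -1.63 ± 0.13, Gbp2 at -1.37 ± 0.16 and Rsad2 at 0.72 ± 0.12, and were called lower without mouse 1 or mouse 3 (adjusted p = 0.0332 and 0.0212), but not with an estimated correlation (adjusted p = 0.467). Fry called this list (adjusted p = 0.00770). Other splits of these libraries that part every mouse gave up to 11 called lists, the most where all mice but 1 kept their real groups. Splits that exchanged the groups in as many mice as they kept gave at most 6 lists. With an estimated correlation between genes, none of the 13 called lists passed (lowest adjusted p = 0.445), and without mouse as a block 7 lists did: the pan-neuronal, mechanoreceptor, regeneration, axon growth, RNA polymerase III and mitochondrial lists lost their calls (adjusted p = 0.0749 to 0.167), as did Nr4a1 and Gal (0.159 and 0.191). Scaled by library size only, 34.0% of the changed genes were higher against 48.7% here, and the median of all genes moved by -0.12.

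**Figure D2:**
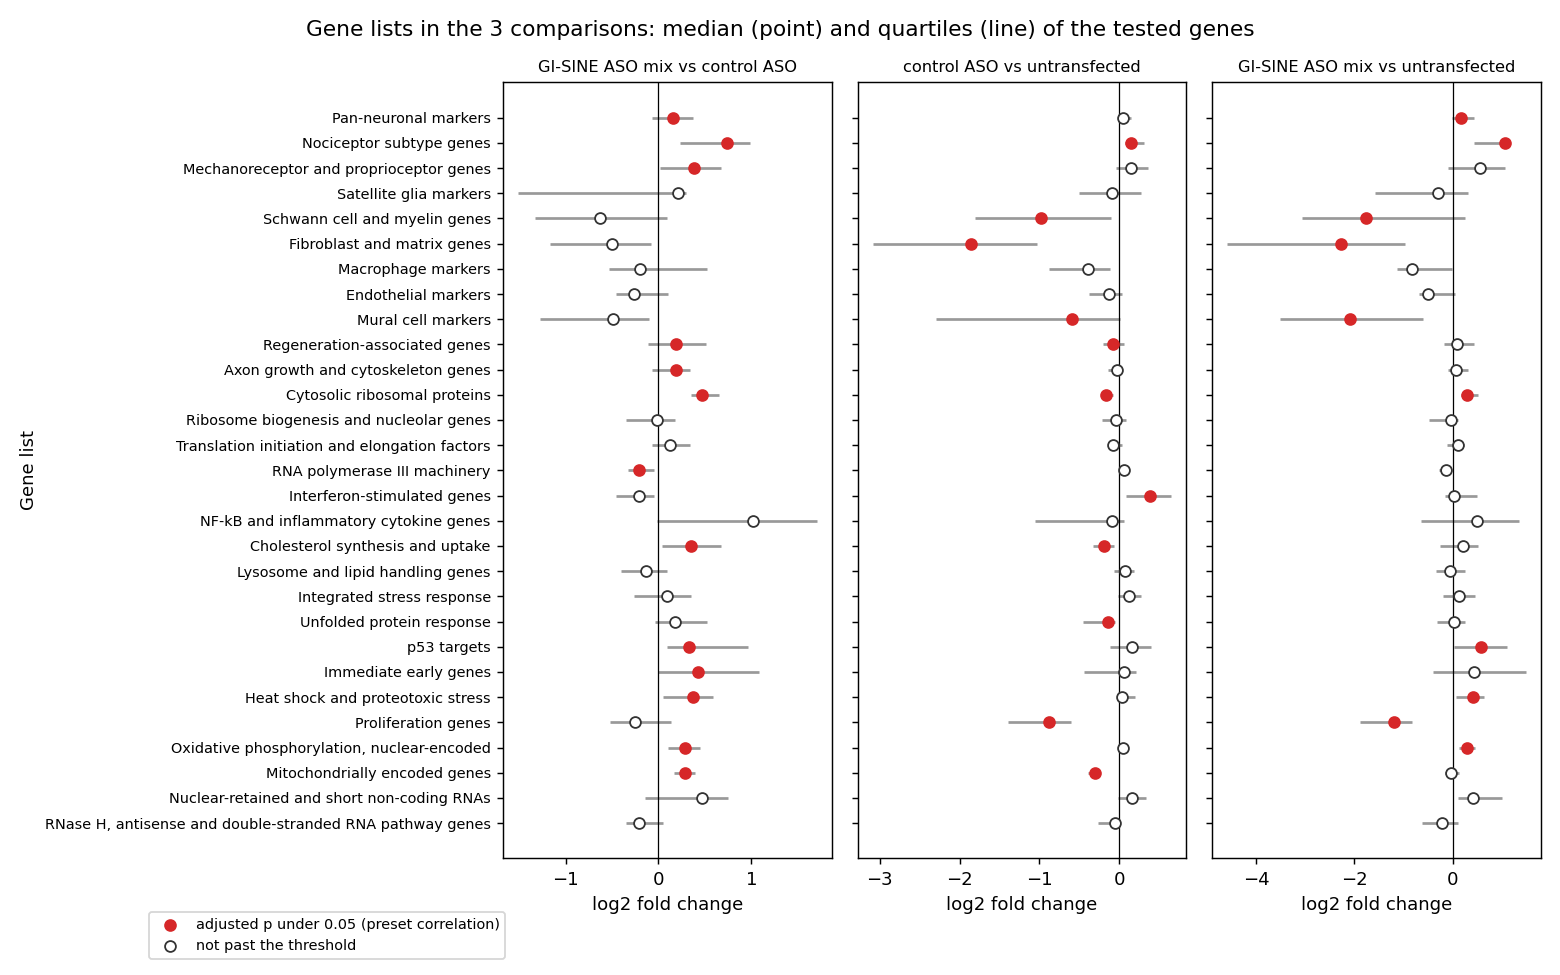
Median log2 fold change (points) and quartiles (lines) of the tested genes of each list in the 3 comparisons, on separate scales, with filled points for lists past an adjusted p of 0.05 in camera at the preset correlation. Fibroblast genes have medians of -0.50, -1.86 and -2.27 from left to right, and ribosomal protein genes 0.47, -0.17 and 0.30.

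The comparison of the control ASO with untransfected cultures measures what changed on transfection with this control ASO. No group was transfected without an ASO, so effects of the procedure and of this ASO cannot be told apart. With the control ASO, 12 of 15 fibroblast genes, 16 of 21 proliferation genes, 10 of 16 Schwann cell genes and 4 of 9 mural cell markers were lower, and 11 of 27 interferon-stimulated genes were higher and 2 lower. With an estimated correlation only the first of these lists kept its call (adjusted p = 0.0363, 0.0665, 0.181, 0.0814 and 0.445 in this order). Col1a1, a chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), fell by 4.16 ± 0.20 on the log2 scale, from 167 ± 12.1 to 9.72 ± 3.77 CPM (adjusted p = 1.95e-06). Gbp2, an interferon-induced GTPase, rose by 1.88 ± 0.16, from 2.44 ± 1.25 to 9.02 ± 3.64 CPM (adjusted p = 9.13e-08). In all, 4081 genes changed, 1775 higher and 2306 lower, with 140 higher and 621 lower by at least 2-fold.

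The largest falls were in Tagln (-5.35 ± 0.48), a smooth muscle gene, Lama2 (-5.29 ± 0.15), Fam198b (-4.27 ± 0.21), Col5a2 (-4.16 ± 0.29), Col14a1 (-4.16 ± 0.26), Col1a1, Cnn2 (-4.12 ± 0.28) and Lpcat2 (-4.06 ± 0.30). The smallest p values belonged to Fbn1, the fibrillin gene (-2.82 ± 0.09, adjusted p = 2.81e-13), Daam2 (-3.85 ± 0.14), Lama2 and Agrn (-2.15 ± 0.08). The largest rises were in Gbp2, Acot1 (1.81 ± 0.26), Tmem140 (1.75 ± 0.16), Ripk4 (1.70 ± 0.22), Baiap3 (1.68 ± 0.36), Fgfbp3 (1.52 ± 0.26), Muc2 (1.45 ± 0.18) and the chemokine receptor gene Cxcr4 (1.30 ± 0.19). Some were scarce in untransfected cultures: Acot1 lay at -0.07 to 0.89 log2 CPM, Ripk4 at -0.29 to 0.89, Baiap3 at -1.69 to -1.18 and Fgfbp3 at -0.80 to 0.71. Baiap3 lay at -0.15 to 0.35 with the control ASO, so it met the required mean log2 CPM only through the mix libraries (1.54 to 2.54). Lpar3 (1.03 ± 0.09) and Ifi30 (1.11 ± 0.11) were among the smallest p values of higher genes.

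Fibroblast and matrix genes were lower in 12 of 15 and higher in none (median -1.86, adjusted p = 1.75e-13, and 0.0363 with an estimated correlation). Col5a1 was at -3.73 ± 0.19 and Mmp2 at -2.16 ± 0.17. Proliferation genes were lower in 16 of 21 (adjusted p = 7.71e-10, and adjusted p = 0.0665 with an estimated correlation), with Top2a at -3.12 ± 0.22, Mki67 at -2.61 ± 0.22 and Rrm2 at -2.33 ± 0.15. Schwann cell genes had 1 higher and 10 lower of 16 (adjusted p = 6.80e-06, and adjusted p = 0.181 with an estimated correlation), with the myelin gene Prx at -2.34 ± 0.12 and Gldn at -1.86 ± 0.09. Mural cell markers were lower in 4 of 9 (adjusted p = 0.00249, and adjusted p = 0.0814 with an estimated correlation), with Cspg4 at -2.29 ± 0.22 and Pdgfrb at -1.20 ± 0.09. Satellite glia, macrophage and endothelial lists had 2, 2 and 1 higher and 4, 2 and 1 lower members. They were not called by camera (adjusted p = 0.319, 0.278 and 0.448), but fry called the satellite glia list lower (adjusted p = 0.0132).

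Smaller shifts were called in 7 other lists, none of which kept its call with an estimated correlation (adjusted p = 0.0665 for the unfolded protein response and 0.445 for each of the other 6). Unfolded protein response genes were lower in 7 of 15 (adjusted p = 0.000358, and adjusted p = 0.0665 with an estimated correlation), with Pdia4 at -0.75 ± 0.06, Pdia6 at -0.61 ± 0.06 and Calr at -0.39 ± 0.05. Ribosomal protein genes were lower in 24 of 74, with Rpsa at -0.34 ± 0.06, and cholesterol genes in 9 of 21, with Cyp51 at -0.68 ± 0.08 and Srebf2 at -0.38 ± 0.06. Regeneration-associated genes had 1 higher and 10 lower of 30, with the cytokine gene Lif at -2.55 ± 0.14. Mitochondrially encoded genes were lower in 1 of 14. Interferon-stimulated genes had 11 higher and 2 lower of 27 (adjusted p = 0.00455, and adjusted p = 0.445 with an estimated correlation), with Rsad2 at 0.60 ± 0.14 and Parp14 at -0.80 ± 0.11. Nociceptor genes were higher in 4 of 17 (median 0.15, adjusted p = 0.0426, and adjusted p = 0.445 with an estimated correlation), a call lost without mouse 3 (adjusted p = 0.0860) and with the length and GC trend removed (adjusted p = 0.124). The ribosomal, cholesterol, mitochondrial and nociceptor lists were not called by fry (adjusted p = 0.0938, 0.0837, 0.123 and 0.0938). Removing the trend kept the calls of the cholesterol and regeneration lists but moved their medians on voom values from -0.19 to -0.12 and from -0.10 to -0.06. Other splits of these libraries that part every mouse gave up to 11 called lists, the most where all mice but 1 kept their real groups. Splits that exchanged the groups in as many mice as they kept gave at most 5 lists. Without mouse as a block, the nociceptor, regeneration and mitochondrial lists (adjusted p = 0.126, 0.0669 and 0.103), Cxcr4 (0.367) and Parp14 (0.0890) lost their calls. The gene count depended on the model: 2391 genes changed without mouse as a block (816 higher, 1575 lower) and 2540 without mouse 3 (752 higher, 1788 lower). Of the changed genes 43.5% were higher, against 55.4% scaled by library size only and 57.8% with the length and GC trend removed.

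**Figure D3:**
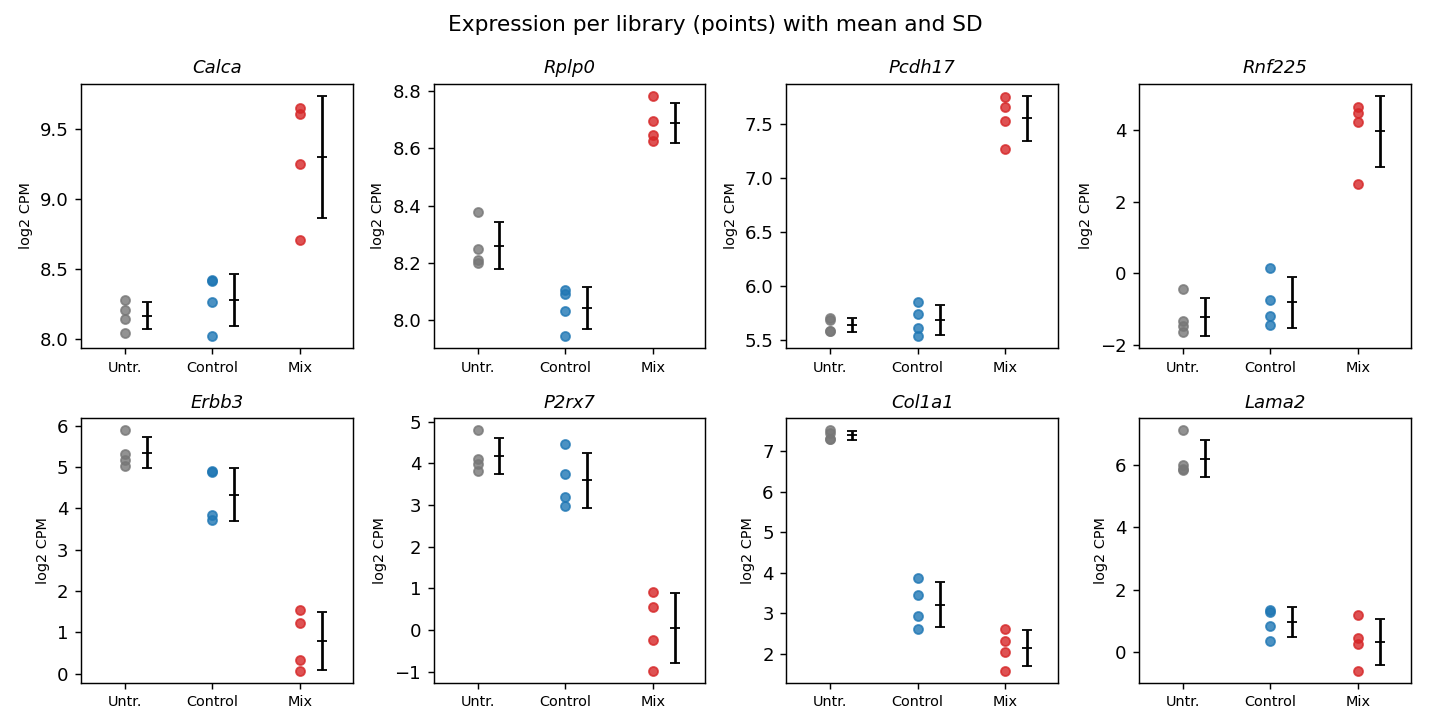
Log2 CPM of 8 genes in each library (points) with the group mean and SD (bars), for untransfected, control ASO and GI-SINE ASO mix cultures, on a separate scale for each gene. Calca, Rplp0, Pcdh17 and Rnf225 are highest in the mix group, and Erbb3, P2rx7, Col1a1 and Lama2 are highest in untransfected cultures.

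The comparison of the GI-SINE ASO mix with untransfected cultures holds both steps together. With the mix, 11 of 15 fibroblast genes and 18 of 21 proliferation genes were lower, and 14 of 17 nociceptor genes and 52 of 74 ribosomal protein genes were higher. These lists were called by camera at the preset correlation and not with an estimated one (adjusted p = 0.270, 0.350, 0.350 and 0.608). In all, 10307 genes changed, 5072 higher and 5235 lower, with 1175 higher and 1077 lower by at least 2-fold. Of the changed genes 49.2% were higher, against 40.8% (4284 higher, 6216 lower) scaled by library size only. The largest falls were in Col5a2 (-6.25 ± 0.34), Olfml2a (-6.16 ± 0.41), Heyl (-6.08 ± 0.50), Lpcat2 (-5.98 ± 0.38), Lama2 (-5.96 ± 0.16), Col8a1 (-5.88 ± 0.31), Loxl3 (-5.86 ± 0.33) and Kirrel (-5.79 ± 0.44). Fbn1 (-3.78 ± 0.09, adjusted p = 7.84e-15), the integrin gene Itgav (-2.88 ± 0.08), Tns3 (-3.58 ± 0.09) and Kank2 (-3.78 ± 0.13) had the smallest p values. The largest rises were in Rnf225 (5.47 ± 0.51), Nhlh1 (5.37 ± 0.36), Zfp750 (5.20 ± 0.71), Rpl3l (4.78 ± 0.34), Fam83e (4.28 ± 0.30), Ptprv (4.21 ± 0.39), Slc25a2 (4.20 ± 0.35) and Ccdc24 (4.14 ± 0.50). All of them lay near the floor of detection in untransfected cultures, such as Zfp750 at -2.71 to 0.82 log2 CPM and Fam83e at -1.69 to -1.32. Fndc9 (3.76 ± 0.16), Pcdh17 (1.92 ± 0.08), Gch1 (2.20 ± 0.10) and Tmem79 (1.80 ± 0.08) had the smallest p values among higher genes.

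At the preset correlation 10 lists were called, 6 higher and 4 lower, and with an estimated correlation none passed (lowest adjusted p = 0.270). Nociceptor genes had 14 higher and 1 lower of 17 (median 1.06, adjusted p = 3.64e-05, and adjusted p = 0.350 with an estimated correlation), with Lpar3 at 1.06 ± 0.09. Lpar3 rose in the step to the control ASO. It lay at 3.10 to 3.75 log2 CPM in untransfected cultures, 4.15 to 4.59 with that ASO and 4.21 to 4.74 with the mix. Pan-neuronal markers had 11 higher and 1 lower of 18 (adjusted p = 0.0117, and adjusted p = 0.418 with an estimated correlation), with Nefm at 0.65 ± 0.06 and Uchl1 at 0.58 ± 0.04. Ribosomal protein genes had 52 higher and 1 lower of 74 (adjusted p = 4.88e-06, and adjusted p = 0.608 with an estimated correlation), with Rpl10a at 1.03 ± 0.11 and Rpl3 at 0.49 ± 0.06. Nuclear oxidative phosphorylation genes had 21 higher of 29, p53 targets 11 higher and 1 lower of 18, and heat shock genes 10 higher and 2 lower of 14 (adjusted p = 3.24e-05, 0.000620 and 0.00601, and adjusted p = 0.418, 0.418 and 0.433 with an estimated correlation). Fibroblast genes were lower in 11 of 15 (median -2.27, adjusted p = 4.88e-06, and adjusted p = 0.270 with an estimated correlation), with Col1a1 at -5.25 ± 0.22. Mural cell markers had 1 higher and 7 lower of 9, with Pdgfrb at -2.47 ± 0.10, and Schwann cell genes 5 higher and 11 lower of 16, with Erbb3 at -4.59 ± 0.18 and Gldn at -2.55 ± 0.09 (adjusted p = 0.0203 and 0.0226, and adjusted p = 0.350 and 0.512 with an estimated correlation). Proliferation genes had 2 higher and 18 lower of 21 (adjusted p = 0.000562, and adjusted p = 0.350 with an estimated correlation). The other lists called between the mix and the control ASO were not called here. Regeneration-associated genes had 12 higher and 9 lower of 30 (camera adjusted p = 0.637). Axon growth genes had 11 higher and 4 lower of 24 (0.297). Cholesterol genes had 10 higher and 6 lower of 21 (0.360), and mitochondrially encoded genes 1 higher of 14 (0.786). Mechanoreceptor, immediate early and RNA polymerase III lists were at 0.0881, 0.0830 and 0.284. Fry called the latter and the axon growth list. Other splits of these libraries that part every mouse gave up to 12 called lists, the most where all mice but 1 kept their real groups. Splits that exchanged the groups in as many mice as they kept gave at most 8 lists. The ribosomal list lost its call with the length and GC trend removed (adjusted p = 0.336, median on voom values from 0.30 to 0.11), and the oxidative phosphorylation list kept its call while its median went from 0.30 to 0.18. The Schwann cell and pan-neuronal lists lost theirs without mouse 4 (adjusted p = 0.0745 and 0.0800) and without mouse as a block (0.106 and 0.0738).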

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

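The tests of the spread of the 6 non-neuronal lists, of length and GC bias in the lists that fell with the control ASO, of the pan-neuronal markers and of upstream genes were chosen after the results were seen. A value was taken to lie apart from the other 3 libraries of its group where its gap to the nearest one, divided by the range of the group, was above Dixon's 95% critical value. Chance gives this in about 1 of 20 groups. Of 483 groups of values, 54 held such a library, and in 46 of these it came from mouse 4. The mix library of mouse 4 had 16416459 counts (20569662 to 21250125 in the other mix libraries) and a scaling factor of 1.00 (0.933 to 0.943 in the others). The mix library of mouse 2 lay below the other 3 where the log2 CPM mean of the list was 2.05 for the interferon-stimulated genes. This library lay above the others where log2 CPM was 3.84 for Lif. The mix library of mouse 3 lay below the other 3 where log2 CPM was 9.40 for Cdkn1a. The mix library of mouse 4 lay below the other 3 where the log2 CPM mean of the list was 5.65 for the nociceptor subtype genes and 4.85 for the cytosolic ribosomal proteins. This library lay below the others where log2 CPM was 0.90 for Ccdc24, 2.06 for Slc25a2, 10.73 for Uchl1, 1.54 for Baiap3 and 3.60 for Zfp750. The same held at 1.73 for Fam83e, 0.70 for Il1a and 3.97 for Nfkbiz. This library lay above the others where log2 CPM was 1.54 for Mmp2, 3.47 for Pdgfrb, 4.65 for Itgav and 2.94 for Relb. The control ASO library of mouse 2 lay above the other 3 where log2 CPM was 2.63 for Fabp7, 5.42 for Postn and 5.17 for Gldn. The control ASO library of mouse 3 lay above the other 3 where the log2 CPM mean of the list was 6.03 for the nuclear oxidative phosphorylation genes. The control ASO library of mouse 4 lay above the other 3 where the log2 CPM mean of the list was 2.85 for the mural cell markers, 5.55 for the p53 targets and 5.13 for the immediate early genes. This library lay above the others where log2 CPM was 6.06 for Aen, 4.78 for Nr4a1, 2.84 for Ripk4, 3.58 for Cxcr4 and 4.15 for Tagln. The same held at 3.86 for Fbn1. This library lay below the others where the log2 CPM mean of the list was 7.20 for the translation initiation and elongation factors and 5.33 for the mitochondrially encoded genes. Its values were also below the others where log2 CPM was 9.61 for Cd44 and 3.41 for mt-Co3. The untransfected library of mouse 2 lay above the other 3 where the log2 CPM mean of the list was 7.35 for the translation initiation and elongation factors. The untransfected library of mouse 4 lay below the other 3 where the log2 CPM mean of the list was 8.40 for the pan-neuronal markers. This library lay below the others where log2 CPM was 8.74 for Sema6a, 11.40 for Dync1h1 and 9.47 for Stmn2. Its values were also above the others where the log2 CPM mean of the list was 5.57 for the Schwann cell and myelin genes, 4.11 for the mural cell markers, 4.82 for the cytosolic ribosomal proteins, 5.41 for the cholesterol genes and 5.35 for the p53 targets. The same held at 5.07 for the immediate early genes. Its values were also above the others where log2 CPM was 1.22 for Bcl6b, 8.55 for Col1a2, 5.89 for Aen, 5.06 for Hsd17b7 and 7.12 for Lama2. The same held at 4.46 for Col14a1 and 5.81 for Prx.

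The real groups were compared with other splits of the 8 libraries of a comparison, with mouse as a block. Of 35 splits, 8 part the libraries of all 4 mice as the real one does, too few for a share under 0.05. By edgeR, the real split of the mix and the control ASO gave 8824 genes (9727 at an unadjusted p under 0.05), and 1 of the 8 gave as many. The highest other gave 0 (1347 unadjusted). For the control ASO and untransfected cultures the real split gave 5995 genes (7313 unadjusted), and again 1 of 8 gave as many, with 0 in the highest other (316 unadjusted). For the mix and untransfected cultures it gave 9518 (10204 unadjusted) and 1 of 8 gave as many, with 0 in the highest other (693 unadjusted). The 24 splits that part fewer mice also gave 0 genes each, with at most 4649, 2360 and 3228 unadjusted in the same order, and 3 splits that follow the mice could not be fitted. These highest unadjusted values came from splits where the parted mice kept their real groups. In every split but the real one, the real difference of some mice enters the spread, so the counts of 0 do not measure chance. No other tool was run on the splits. Counts of lists called by camera at the preset correlation differed far less between splits. The real split of the mix and the control ASO gave 14 lists, 1 of 8 gave as many, and the highest other gave 11. For the control ASO and untransfected cultures it gave 15, 1 of 8 gave as many, and the highest other gave 11. For the mix and untransfected cultures it gave 10, 2 of 8 gave as many, and the highest other gave 12. Among the 8, the highest others kept the real groups of all mice but 1. Those that exchanged the groups in as many mice as they kept gave at most 6, 5 and 8 lists. Splits that part fewer mice gave up to 17, 13 and 11 lists, all where the parted mice kept their real groups. Where the parted mice opposed each other, the most were 5, 3 and 8 lists. Camera at this setting thus also called lists where the groups were mixed.

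Between the mix and the control ASO, 9454 genes changed, and length and GC bias as the whole cause is argued against by the 83.2% of them (7865) that stayed called in the same direction once each library's trend was removed. For a loss of other cells as the whole cause, the test set beforehand did not decide: it asked for at least 10% of neuronal list members in each direction, and of 50 members 30 were higher and 3, or 6%, were lower. A test chosen after that argues against it, if the 18 pan-neuronal markers come from neurons only: it would move them alike, and they moved apart, from -0.26 to 0.73 for Snap25 (permutation of markers within each mouse, p = 9.9999e-06, the smallest that 100000 permutations can give). For the 836 genes at least 2-fold higher, a larger share of all neurons alike is argued against by the median of these markers, 0.16 (quartiles -0.06 and 0.37), which lies below the 1 it would need. A change in the mix of neuron types, and effects of the ASO mix on its target or on other RNAs, stay open and untested.

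Fibroblast, Schwann cell and mural cell lists were called lower with the control ASO at the preset correlation, and only the first with an estimated one (adjusted p = 0.0363, 0.181 and 0.0814). Length and GC bias is argued against by the combined median of their 40 tested members, -1.32 with the trend removed (quartiles -2.21 and -0.21) and -1.31 before. The spread of the 6 list medians argues against an equal loss of every non-neuronal cell type only if each marker comes from its cell type alone. Ngfr, which sensory neurons also express, does not meet this. The medians ran from -1.86 for fibroblast to -0.09 for satellite glia genes (permutation p = 0.0384, one-sided for a larger spread, over genes, which are not independent replicates). The satellite glia list had 2 higher and 4 lower members and a mean of -0.34, and fry called it lower (adjusted p = 0.0132). In the mix against the control ASO neither test decided: the spread gave a permutation p = 0.409, and the combined median of satellite glia, Schwann cell and fibroblast genes was -0.45 before and -0.44 with the trend removed, above the bound of -0.5 in both cases. Unequal loss of cell types and lower expression within cells that stayed are both open and untested.

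Of the 836 genes that the mix raised by at least 2-fold, 717 lay under the median abundance. Whether reads running on from an upstream gene account for a part of these stays open: the 954 scarce genes with only an upstream neighbour (a more abundant gene on the same strand within 10 kb) had a median log2 fold change 0.12 above that of the 602 with only a downstream one (permutation p = 0.00457, two-sided, over genes), but only 0.01 above that of the 5856 with neither (-0.04 against -0.05, permutation p = 0.798). Between the control ASO and untransfected cultures the first difference was 0.07 (permutation p = 0.00200). Called rises of at least 2-fold were in 13.6% of the 954 against 6.81% and 6.93%, and of the 717 genes 22.5% had an upstream neighbour with or without a downstream one (14.1% of other scarce genes), 15.2% overlapped a more abundant gene of the same strand and 56.6% had neither neighbour. Reads of a gene on the other strand may contribute, since 32.4% of the 717 overlapped a tested gene there against 21.4% of other scarce genes, a ratio of 1.51 (95% interval 1.35 to 1.70) whose lower limit is under the 1.5 set beforehand, while regulation of the genes themselves stays open and untested.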

How the results depend on the processing

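Scaling by library size only, removal of the length and GC trend and leaving out the 3 most abundant loci were added after the data were seen. Of 2108 values of named genes under the alternatives, 2097 kept their direction and side of the threshold, 11 kept their direction and lost the call, and none reversed. These genes were picked from the same data for a small p or a large change, so they say little of the other genes. Of all called genes, the fit without the block kept 7953 of 9454 for the mix against the control ASO. It kept 2388 of 4081 for the control ASO and 9159 of 10307 for the mix against untransfected cultures. Without mouse as a replicate block, Nr4a1, Gal and Ptgs2 lost the call between the mix and the control ASO, and Cxcr4, Itga7, Cd44, Parp14, Prdm12 and mt-Co3 between the control ASO and untransfected cultures. In the latter comparison mt-Co3 also lost it without mouse 2 or 3 (adjusted p = 0.0584 and 0.0539 in edgeR). Of 306 values of called lists, 245 stayed called, 61 lost the call and none reversed. Asking for a 1.5-fold change as well left 3490 genes for the mix against the control ASO, 1379 for the control ASO against untransfected cultures and 4643 for the mix against untransfected cultures, a subset by construction. Without the block for mouse, 2391 genes changed between the control ASO and untransfected cultures (4081 with it), and 7 lists between the mix and the control ASO (13 with it). With an estimated correlation, camera called 0 lists for the mix against the control ASO (0 at an unadjusted p under 0.05), 1 for the control ASO against untransfected cultures (5 unadjusted) and 0 for the mix against untransfected cultures (4 unadjusted). Fry, which does not compare a list with other genes, called 23, 11 and 21 in the same order, not all of them the lists called by camera: 1 and 4 called lists lost their call in the first 2 comparisons and none in the third. Other than for the 1.5-fold change, the cause was not tested. Leaving out each mouse gave 7390 to 10217, 2540 to 3946 and 8857 to 10770 genes and 14 to 16, 10 to 13 and 10 to 11 lists, with 2540 without mouse 3. Without mouse 4, whose libraries often lay apart, the gene counts were 10217, 3946 and 10770. Depth limits scarce genes: the 8 largest rises with the mix start from means of 0.207 to 0.823 CPM.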

Other observations

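The comparison of slopes between mice was chosen after the result was seen. Between the mix and the control ASO, the list of NF-kB targets and inflammatory cytokines had 8 higher and 2 lower of 15 (median 1.02, camera adjusted p = 0.0988, not called, and fry adjusted p = 0.0121, called). Within it the cytokine gene Il1a was at 5.84 ± 0.50 on the log2 scale (SE, 4 mice), from 3 counts over the control ASO group to 184 over the mix group, and Nfkbiz, an NF-kB regulator, at 1.53 ± 0.14. Relb, a subunit of NF-kB, was at -0.69 ± 0.13 and the prostaglandin synthase gene Ptgs2 at -1.40 ± 0.25, with no call for Ptgs2 without mouse as a block (adjusted p = 0.0850 in edgeR). These 4 genes moved in their direction in all 4 mice.

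The following lists held members in both directions in this comparison, and camera at the preset correlation, with the scaling used throughout and all 4 mice, did not call them. Translation factors had 13 higher and 5 lower of 25 (adjusted p = 0.0518), with Eif6 at 0.59 ± 0.06, and unfolded protein response genes 9 higher and 3 lower of 15 (adjusted p = 0.0538), with Herpud1 at 0.45 ± 0.06. Both lay near the threshold. Translation factors were called higher without mouse 2, 3 or 4 (adjusted p = 0.0453, 0.0381 and 0.0490), with DESeq2 size factors (adjusted p = 0.0463) and with the length and GC trend removed (adjusted p = 0.0168). Unfolded protein response genes were called higher without mouse 1, 2 or 3 (adjusted p = 0.0480, 0.0453 and 0.0381), with DESeq2 size factors (adjusted p = 0.0481) and with the trend removed (adjusted p = 0.0259). Neither passed with an estimated correlation (adjusted p = 0.467 and 0.445). Fry called these 2 lists and the next 4 (adjusted p = 0.000760 to 0.0299). Integrated stress response genes had 8 higher and 7 lower of 19 (adjusted p = 0.399), with the transcription factor gene Atf4 at 0.52 ± 0.05. Nucleolar genes had 6 higher and 12 lower of 26 (adjusted p = 0.473), with Noc2l at 0.82 ± 0.07 among the higher ones. Lysosome genes had 4 higher and 11 lower of 19 (adjusted p = 0.206), with Lamp1 at 0.43 ± 0.05 and the protease gene Ctsd at 0.32 ± 0.05 among the higher ones. Genes of the RNase H, antisense and double-stranded RNA pathways had 3 higher and 8 lower of 17 (adjusted p = 0.234), with the microRNA processing enzyme Drosha at 0.59 ± 0.06 and the RNA editing enzyme Adar at -0.56 ± 0.06. Nuclear-retained and short non-coding RNAs had 6 higher and 1 lower of 11 (adjusted p = 0.226), with Snhg1 at 0.61 ± 0.13, and proliferation genes 4 higher and 5 lower of 21 (adjusted p = 0.839).

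Genes with a B2 sequence in the 3' UTR were lower with the mix when it lay in the sense direction. Of tested genes with a 3' UTR, 275 had a sense match only, 193 an antisense match only and 13573 none. Between the mix and the control ASO their median log2 fold changes were -0.44, -0.17 and -0.05, and 65.5%, 45.1% and 31.5% of them were called lower. The difference between sense and antisense genes was -0.27 (permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give), and -0.29 with the length and GC trend removed. Between the control ASO and untransfected cultures it was 0.03 (permutation p = 0.180). A hypothesis consistent with this test is that the ASO mix also lowers mRNAs with a sense B2 sequence. The antisense genes lay below those with no match too, which this hypothesis alone does not give. Median 3' UTR lengths were 2388, 2816 and 1348 bases, the consensus was written from general knowledge, and genes are not independent replicates.

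The mix moved the culture of mouse 4 less than the others. Across tested genes, the slope of a mouse's log2 difference between mix and control ASO on the mean difference of the other mice was 1.06, 1.06 and 0.958 for mice 1 to 3 and 0.502 for mouse 4. Between the control ASO and untransfected cultures it was 0.930, 0.779, 0.876 and 0.830. The difference between mice was not tested.

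Of the genes lower with the control ASO than in untransfected cultures, 866 were lower again with the mix, against 665 for independent lists, and 643 were higher in both steps, against 485. In opposite directions, 544 were higher with the control ASO and then lower with the mix, against 512, and 503 lower and then higher, against 630. Both steps use the control ASO libraries. In 10 simulations of groups with no change edgeR gave 0 genes higher or lower in both (means of 1 and 0.4 at an unadjusted p under 0.05), which is chance with no effect and says nothing of lists that hold real changes. With the control libraries divided between the steps, 1038 genes were lower in both against 693 for independent lists and 975 higher against 623 (mix step in mice 1 and 2), and 246 against 142 and 249 against 138 (mix step in mice 3 and 4). Higher and then lower were 575 against 613 and 139 against 93.8, and lower and then higher 521 against 705 and 186 against 209.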
